A study of Homo sapiens with 5 samples.

How the data were processed

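The deposited table holds 1 column per library and 24549 rows, of which 52 are ERCC spike-ins and 24497 are gene symbols. Its values are whole-number counts per gene, as deposited by the authors, with no normalization. Per the submitters' processing notes, cutadapt 1.2.1 and STAR 2.4.0a were used with the builds hg19 and GRCh37. The labels' protocols describe lysis of 1000 cells, use of the product of 100 cells for 18 cycles of PCR, and a template-switching oligonucleotide with a molecular identifier of 4 N and 4 H bases. How reads became counts, whether identifiers were collapsed, which gene annotation served and whether strand was used are not given in the sources used here. If reads were not collapsed to molecules, intervals and limits from counts understate the error, and in either case they cover counting error only. Reads of pseudogenes, paralogs and overlapping genes may be shared between rows.

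Columns were assigned to batches by the prefix they share with the sample titles, and the numbers that end them were used only as names of libraries. No column was left unused. The depth was 373687 to 803168 gene counts per library, so that a gene with 0 counts may have up to 8.03 CPM in the shallowest and 3.74 CPM in the deepest library, taking 3 counts as the limit. CPM values were computed from gene counts without spike-ins.

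Batch B was compared with batch A with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the filter filterByExpr with batch as group, and the quasi-likelihood F test with batch as the only term. This left 9215 genes with 97.1% of gene counts. Benjamini-Hochberg adjusted p under 0.05 was a call. The prior degrees of freedom were estimated as infinite for all 9215 genes, so the spread was pooled over genes of like abundance, and a gene with an unusual spread of its own, such as MALAT1, is tested against that pooled value. Standard errors of log2 fold changes are the fold change divided by the square root of F. In fits that leave a single batch A library, that library is assumed to vary like those of batch B.

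The 28 gene lists, the tests and the rule for naming genes were set before the data were examined. Lists with at least 5 tested members, 23 in all, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with the correlation estimated, and with fry. Camera called 3 lists, and 4 had an unadjusted p under 0.05. With an estimated correlation 0 were called. Fry called 0 lists for a shift in one direction and 9 for changes in either direction. Named genes are the 12 largest rises and 12 largest falls among called genes with libraries that do not overlap, the 10 most abundant genes, up to 3 called members of each list by smallest p, the 2 members of highest CPM in lists without a called member, and the 3 spike-ins of highest mean count. Genes named outside that rule are said to be chosen after their values were seen.

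Shares, spike-ins and genes detected were compared with exact two-sided permutation tests over the 10 splits of the libraries. Shares have exact Clopper-Pearson intervals at 95%. Genes detected are means over 20 seeded draws of binomial thinning. The gene test after thinning used a single seeded draw, so calls near the threshold may differ in another draw. Pairs of libraries were compared over genes with a pair sum of at least 20 and with a pseudocount of 1 CPM. Spike-ins were tested with edgeR when their total was at least 10. A planned test with libraries scaled to the spike-ins is not reported, because that scaling centers the spike-ins themselves and rests on 33 counts in batch B. Transcript length, GC content and biotype came from GENCODE release 29, matched by name only for 18866 of the gene rows. That annotation is on another build than the deposited data, so no coordinates are given. Of the tested genes 97.5% and of the called genes 92.2% had a GC value.

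The edgeR test was tested on simulated data drawn from the means and depths of these libraries, over 8911 genes for batch B against batch A. It found 22 of 67 genes changed 1.5-fold (32.8%), 53 of 67 changed 2-fold (79.1%) and 66 of 66 changed 4-fold, with 6 false calls (4.08% of calls). The changed genes were drawn only from those with an expected mean count of at least 20, so recovery at lower counts is not covered. On simulated data with no change, 0 of 8900 genes and 0 lists were called. Genes were simulated independently and with a common dispersion. This therefore cannot show how often lists of correlated genes, or genes with a spread of their own, are called without a change. In the data the estimated correlation was 0.82 for ribosomal protein genes and 0.74 for mitochondrially encoded mRNAs. An imposed GC trend gave 1090 calls over 9239 simulated genes before and 0 after its removal.

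Alternatives set before the data were examined were DESeq2 size factors, library totals, spike-in scaling, the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts, a mean count of at least 20, thinning, correction for identifier collisions, and leaving out each library in turn. Alternatives chosen after the data were seen removed trends with GC content, transcript length or abundance from each library by loess, or mapped counts back through a simulation in which identifiers 1 mismatch apart are merged, or combined an estimated correlation with leaving out a library or with one of these corrections.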

Results

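Gene expression was profiled in HEK293 cells, an established human line derived from embryonic kidney, with RNA sequencing that selects the 5' ends of transcripts and primes reverse transcription with oligo-dT. Each library carried the material of 100 cells, amplified from a lysate of 1000 cells. The labels name 2 libraries in batch A and 3 libraries in batch B, and no treatment. The deposited columns end in the numbers 2 and 3 for batch A and 1, 2 and 3 for batch B, and libraries are named here by those numbers. In batch A they do not match the replicate numbers of the labels, so they are not taken as replicate numbers in either batch. Gene counts came to 686883 and 803168 in batch A libraries 2 and 3, and to 373687, 575472 and 685181 in batch B libraries 1, 2 and 3. The labels do not say whether the libraries came from separate cultures, so all p-values measure only the spread between these libraries, which may be technical.

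The replicate design raises the question of how closely libraries of one batch agreed and how far the batches lay apart. The 10 most abundant genes were all mitochondrially encoded, led by MT-CO2, a subunit of cytochrome c oxidase, at 2966 ± 249 CPM in batch A (SD, n = 2) and 4115 ± 919 CPM in batch B (SD, n = 3). They included MT-RNR2, the large ribosomal RNA of the mitochondrion. Across genes, Pearson's r of log2(CPM + 1) was 0.939 to 0.960 for the 4 pairs of libraries within a batch and 0.940 to 0.956 for the 6 pairs between batches, and genes are not independent replicates. The chi-square statistic per degree of freedom is 1 if independent counts vary by sampling alone. It was 1.21 to 1.61 within a batch and 1.95 to 2.65 between batches, so no pair agreed within sampling noise of that kind. Whether reads were collapsed to molecules is not known, so noise alone may give a value above 1. The mean of the statistic was 1.35 within and 2.24 between batches, and 1.69 and 3.68 over genes with a pair sum of at least 100. The common biological coefficient of variation was 5.34% in batch A and 7.22% in batch B. Genes of high count differed less between libraries than depth would give. The median log2 ratio of batch B library 3 to library 1 was 0.95 over 3228 genes with a mean count of 20 to 50, 0.66 over 63 genes with a mean count of 800 to 1200, and 0.26 over the 7 genes with a mean count of 1600 to 2500. The highest count of any gene in any library was 2293.

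**Figure D1:**
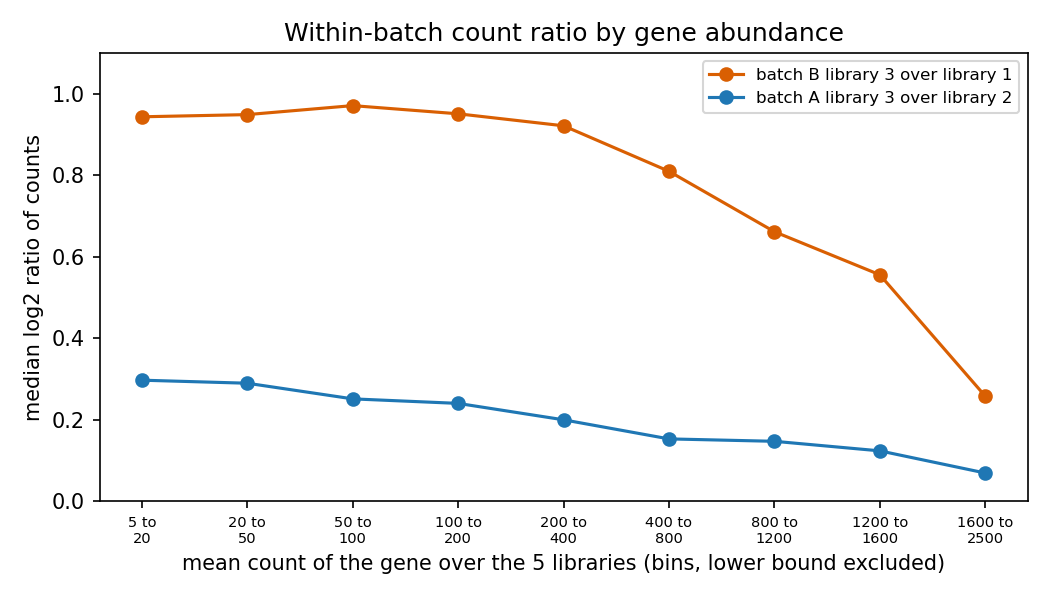
Median log2 ratio of counts between 2 libraries of one batch (vertical axis) for genes binned by their mean count over the 5 libraries (horizontal axis), with one line for batch B and one for batch A. The ratio of batch B library 3 to library 1 was 0.94 in the lowest bin and 0.26 in the highest, and that of batch A library 3 to library 2 was 0.30 and 0.07; the highest bin holds 7 genes.

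The breadth and make-up of the libraries were compared between batches at the level of gene classes. Mitochondrially encoded mRNAs took 2.67% ± 0.185 of gene counts in batch A (SD, n = 2) and 3.77% ± 0.713 in batch B (SD, n = 3). Cytosolic ribosomal protein genes took 11.8% ± 0.507 in batch A and 12.7% ± 0.926 in batch B. The 10 most abundant genes took 2.4% ± 0.16 in batch A and 3.5% ± 0.75 in batch B. Exact two-sided permutation tests gave p = 0.2, 0.4 and 0.2 for the 3 classes, and the 10 splits of 2 against 3 libraries allow no p under 0.1. After thinning to the smallest library, 14045 ± 202 genes had a count in batch A and 14130 ± 149 in batch B (SD, n = 2 and 3), a difference within the spread of the libraries (exact permutation p = 0.6). That difference of 84.5 genes became -58.2 without batch A library 2, 227 without batch A library 3, 167 without batch B library 1 and 22.4 without batch B library 3, and without thinning it was -734, which follows depth. The share of mitochondrially encoded mRNAs was 4.55% (95% exact binomial interval 4.49 to 4.62) in batch B library 1, the shallowest, and 2.54% (2.51 to 2.58) in batch A library 3, the deepest. The difference of 1.09 percentage points in that share was 0.701 without batch B library 1. That of 0.882 points for ribosomal protein genes was 0.430 without batch B library 1, 0.524 without batch A library 3 and 1.36 without batch B library 3, and that of 1.1 points for the 10 most abundant genes was 0.684 without batch B library 1. With counts mapped back through simulated merging of identifiers, a setting chosen after the data were seen, the difference for ribosomal protein genes turned to -1.48 points, and those for mitochondrial mRNAs and the 10 most abundant genes were 3.28 and 3.77 (exact permutation p = 0.2, 0.1 and 0.1). Without the 10 most abundant genes that for mitochondrial mRNAs was 0.151 points (exact permutation p = 0.2).

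Per the labels' protocols, whose text is the same for both batches, an ERCC spike-in mix of synthetic polyadenylated RNAs was in the lysis buffer at 20000 molecules per cell, and spike-in counts were compared between the batches. No label tells whether the mix was left out of batch B, so ratios of spike-in counts need not reflect an equal input. ERCC-00074 had 841 counts over batch A and 6 over batch B, ERCC-00130 had 715 and 7, and ERCC-00002 had 490 and 6. Their log2 fold changes on the scale of the endogenous genes were -7.17, -6.72 and -6.39, with edgeR adjusted p = 0.000113, 8.7e-05 and 8.7e-05. All spike-ins together took 0.262% ± 0.00349 of counts in batch A (SD, n = 2) and 0.00214% ± 0.00174 in batch B (SD, n = 3), a ratio of mean shares of 122 with every batch A library above every batch B library. The exact two-sided permutation test gave p = 0.1, the smallest that 2 against 3 libraries allow. Batch B held 33 spike-in counts in all, of which 13, 1 and 19 fell in libraries 1, 2 and 3, where 4280 would be present at the share of batch A. The pooled shares differed 130-fold (95% interval 92.2 to 189). All 19 spike-ins tested with edgeR had negative fitted log2 fold changes on the scale of the endogenous genes, and 16 of them were called. ERCC-00085, singled out after its values were seen and too low in total for edgeR, had 0 of 3912 spike-in counts in batch A and 5 of 33 in batch B. Fisher's exact test on the pooled counts gave p = 2.99e-11. That test treats counts as independent, and the spike-in was picked for its counts, so the p-value overstates the evidence. Intervals cover counting error only.

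**Figure D2:**
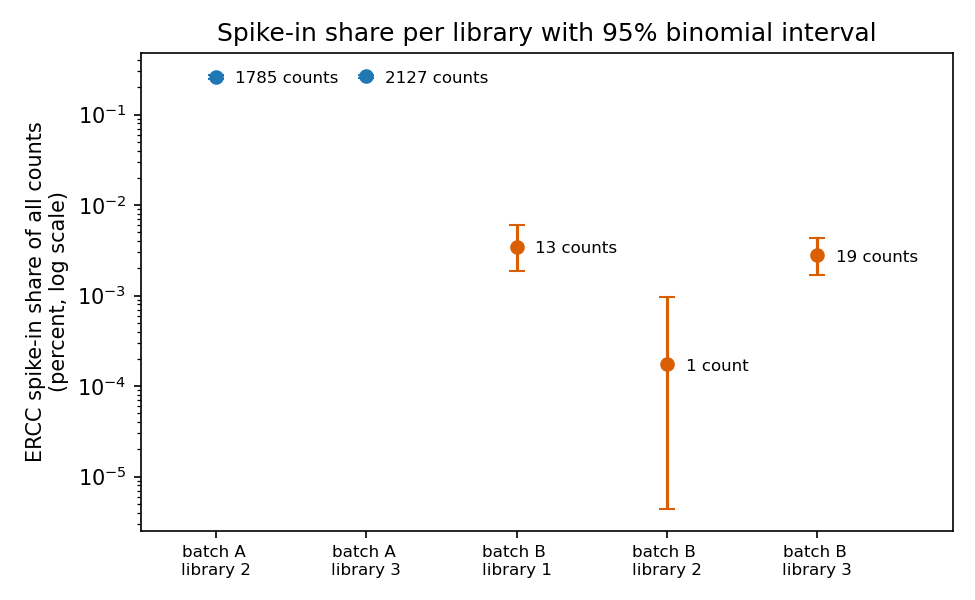
Share of ERCC spike-ins among all counts (vertical axis, percent, log scale) in each of the 5 libraries, with 95% exact binomial intervals as bars and the number of spike-in counts beside each point. Both batch A libraries lie near 0.26%, and the batch B libraries lie at 0.00348%, 0.000174% and 0.00277%.

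The comparison of gene expression between batch B and batch A asks which transcripts differ when the same line is profiled in another batch. Among the largest rises in batch B were 4 mitochondrial tRNAs, of which MT-TS2, a serine tRNA, was the most abundant, at 60.3 ± 9.5 CPM in batch A and 334 ± 13.5 CPM in batch B, and MT-TI, an isoleucine tRNA, had the largest fitted rise, at 3.11 ± 4.4 and 33.6 ± 5.35 CPM (SD, n = 2 and 3). SNORD13, a small nucleolar RNA, rose 5.92-fold, from 32.1 ± 2.15 to 186 ± 18.9 CPM. Reverse transcription was primed with oligo-dT. The counts do not show whether reads on the tRNA and SNORD13 rows came from the mature RNAs or from longer or overlapping transcripts. NDUFAF4, an assembly factor of mitochondrial complex I, was 3.29-fold lower in batch B, at 540 ± 52 against 159 ± 11.6 CPM. KRT81, a hair keratin, had 23 counts over batch A and 0 over batch B, at least 8.41-fold lower at the level that 3 counts over the group would give. EGR1, an immediate-early transcription factor, rose 2.83-fold, and PGAM1, a glycolytic phosphoglycerate mutase, was 1.97-fold lower.

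By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 387 of 9215 tested genes differed, of which 198 were higher and 189 lower in batch B. The median absolute log2 fold change of the called genes was 0.66, and 80 of them passed 2-fold, 50 higher and 30 lower. In 381 of the 387, all batch B libraries lay on one side of both batch A libraries, against 2882 of all tested genes (31.3%) and 20% by chance. The calls were made on these same libraries, so their separation follows largely from the selection and is no separate evidence. The count of calls depended on the test, on depth and on single libraries. It was 111 with the DESeq2 Wald test (64 higher and 47 lower, of 3150 genes given an adjusted p) and 178 after thinning to the smallest library (96 and 82). Of the 387 genes, 111 were called by DESeq2 and 162 after thinning. Without a filter on low counts 121 genes were higher and 138 lower. With GC and length trends removed, a setting chosen after the data were seen, 120 were higher and 180 lower. The count was 138 without batch A library 2, 152 without batch A library 3 and 202 without batch B library 2, and 63 of the 387 genes were called in all 5 fits that left out a library. Calls of the genes named by rule were lost 99 times over these fits, 67 times with a log2 fold change nearer to 0 and 32 times with one at least as far from it.

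**Figure D3:**
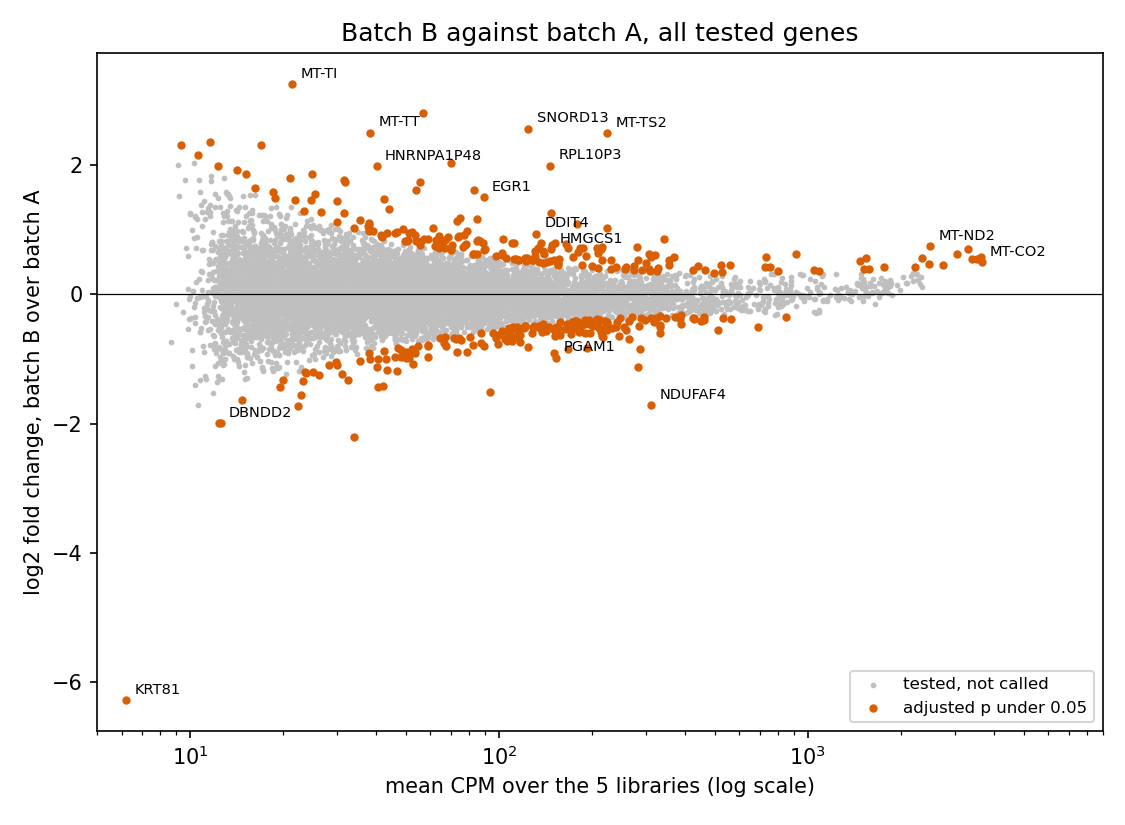
Log2 fold change of batch B over batch A (vertical axis) against mean CPM over the 5 libraries (horizontal axis, log scale) for the 9215 tested genes, with called genes in orange and some named genes labelled. There are 198 called genes above the line and 189 below it; the fitted value of KRT81, which has 0 counts in batch B, depends on the prior count and is no bound.

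The 12 largest rises among called genes with libraries that did not overlap ran from MT-TI, with a log2 fold change of 3.26 (SE 0.56), to HNRNPA1P48, at 1.98 (SE 0.33). Besides MT-TI, MT-TT (2.51), MT-TS2 (2.49), MT-TH (2.31) and SNORD13 (2.57), they were the processed pseudogenes RPL10P15 (2.03), RPL10P3 (1.99) and RPS21P4 (2.35) and the clone-named rows RP11-220D10.1 (2.81), RP11-538P18.2 (2.32) and AC006509.7 (2.15). After KRT81, the largest falls were RP11-384C4.3 at -2.22 (SE 0.32), RPL23AP3 at -1.99, DBNDD2 at -1.99, RPL4P4 at -1.73, NDUFAF4 at -1.72 (SE 0.12), RPL21P28 at -1.63, CTD-2319I12.1 at -1.56, AC004057.1 at -1.51, AL354822.1 at -1.44, RP11-106A1.2 at -1.43 and AC020983.5 at -1.42. NDUFAF4 had an edgeR adjusted p = 2.95e-46 and 396 and 404 counts in batch A against 55, 98 and 110 in batch B. Calls were lost without either batch A library for RPS21P4 (edgeR adjusted p up to 0.366), AC006509.7 (0.508), RPL23AP3 (0.254, also without batch B library 2), DBNDD2 (0.377, also without batch B library 3), RPL21P28 (0.431, also without batch B library 1 or 3) and AL354822.1 (0.210, also without batch B library 1 or 2). That of MT-TH was lost without batch A library 2 (1.68, edgeR adjusted p = 0.224), that of CTD-2319I12.1 without batch A library 3 (0.201) and that of RPL4P4 without batch A library 3 or batch B library 2 (up to 0.192). KRT81 passed the low-count filter in 2 of those 5 fits and RP11-538P18.2 in 1. Without batch A library 2 the log2 fold change of MT-TI was 2.42, below the 2.68 of MT-TS2, and without batch A library 3 it was 7.28, a fitted value against a count of 0 that is no bound. Without batch A library 3 that of RP11-220D10.1 was 3.81, of MT-TH 3.84, of RPS21P4 3.42, of AC006509.7 3.22 and of RPL10P15 2.63, and without batch B library 3 that of RPL4P4 and of AL354822.1 was -2.33 each. When libraries were thinned, in a single draw, calls were lost for HNRNPA1P48 (1.38, edgeR adjusted p = 0.0508), CTD-2319I12.1 (0.102) and RPL21P28 (0.190). With limma-voom MT-TI was at 3.91 and KRT81 at -4.05, and calls were lost for RPS21P4 (adjusted p = 0.121), RP11-538P18.2 (0.153), MT-TH (0.0638), AC006509.7 (0.181), RPL23AP3 (0.0665), DBNDD2 (0.0636), RPL21P28 (0.0832) and AL354822.1 (0.0525). RP11-538P18.2 and AC006509.7 were also lost without a filter on low counts (edgeR adjusted p = 0.0739 and 0.0705) and with library totals (0.0525 and 0.0534). With a transcript length trend removed, a setting chosen after the data were seen, MT-TS2 was at 1.62, MT-TT at 1.68, MT-TI at 2.46 and SNORD13 at 1.94 (1.56, 1.65, 2.44 and 1.89 with the GC trend removed too), and MT-TH lost its call (1.51, edgeR adjusted p = 0.141). Rows of ribosomal protein pseudogenes may share reads with near-identical copies, which the counts cannot show, so they are reported as uncertain.

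Of the 13 mitochondrially encoded mRNAs, which encode subunits of the respiratory chain and ATP synthase, 11 rose in batch B and 2 did not pass the test, 11 also when adjusted over the list alone. Their median log2 fold change was 0.54. Camera called the list as higher (adjusted p = 8.71e-06), and the call was lost with the correlation estimated from the data (adjusted p = 0.809 with an estimated correlation) and with fry (adjusted p = 0.330). MT-ND2, a complex I subunit, rose most, by 0.75 (SE 0.13, edgeR adjusted p = 9.23e-07), from 1793 ± 89.7 to 2964 ± 661 CPM (SD, n = 2 and 3). MT-ATP6 rose by 0.62, MT-ND4 by 0.58, MT-ND3 by 0.56, MT-CYB by 0.55, MT-CO3 by 0.54, MT-CO2 by 0.50, MT-CO1 by 0.47 and MT-ND1 by 0.45 on the log2 scale. MT-RNR2 rose by 0.70 (edgeR adjusted p = 2.02e-05).

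In the 5 fits that left out a library, MT-ND2 and MT-RNR2 were called in all, and MT-CO1, MT-CO2 and MT-ND1 only without batch B library 3 (edgeR adjusted p up to 0.245, 0.331 and 0.387 in the others). MT-CO3 and MT-CYB lost their calls without batch A library 3, batch B library 1 or batch B library 2 (up to 0.244 and 0.236), MT-ND4 without batch A library 3 or batch B library 1 (up to 0.175), and MT-ATP6 and MT-ND3 without batch A library 3 (0.0955 and 0.173). Without batch B library 1 the log2 fold changes were 0.29 for MT-CO2, 0.35 for MT-ND4, 0.27 for MT-ND1, 0.34 for MT-CO3 and 0.36 for MT-CYB. DESeq2 called MT-ND2, MT-ND3 and MT-ND5, the last named after its values were seen, among the mRNAs and did not call MT-RNR2 (adjusted p = 0.0533), nor the other 7 mRNAs named above (0.0700 for MT-ATP6 to 0.264 for MT-CO2). In batch A library 2 and batch B library 3, a pair of nearly equal depth chosen after its values were seen, all 13 mRNAs had higher counts in batch B, with a median log2 ratio of 0.16. A leveling-off of high counts would make this ratio smaller. Of the 13 tested mitochondrial tRNA rows, a group chosen after its values were seen, 10 rose, with a median log2 fold change of 1.73 over the 13. With the length trend removed 5 of the 13 were called and the median was 0.92. MT-TP, a proline tRNA, had 85 and 127 counts in batch A and 89, 175 and 204 in batch B, and rose by 1.03 (SE 0.13).

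**Figure D4:**
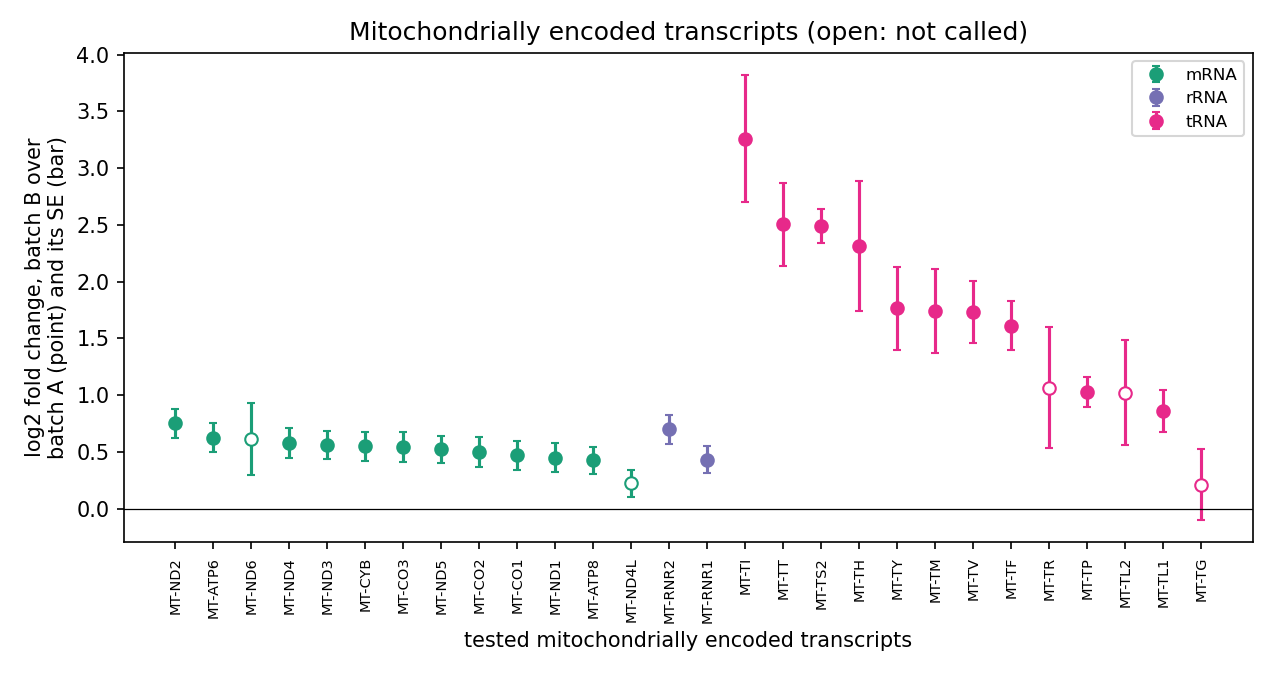
Log2 fold change of batch B over batch A (points) with its standard error (bars) for each tested mitochondrially encoded transcript (horizontal axis), colored by kind, with open points for transcripts that were not called. The mRNAs lie between 0.22 and 0.75 and the tRNAs between 0.21 and 3.26.

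Genes of protein synthesis and of the nuclear-encoded respiratory chain showed changes in both directions. Of 78 tested cytosolic ribosomal protein genes, 4 rose and 1 fell, with a median log2 fold change of 0.13. RPL26 rose by 0.62 (edgeR adjusted p = 1.5e-05), RPS10 rose by 0.43 and RPL17 fell by 0.50 on the log2 scale, and the other called members were RPS9 and RPL8, named after their values were seen. Among 34 translation factors 3 rose, namely the helicase EIF4A1 (0.61), the elongation factor EEF2 (0.42) and the initiation factor subunit EIF3B (0.38). Of 72 nuclear-encoded genes of oxidative phosphorylation, 4 rose and 3 fell. NDUFA13, a complex I subunit, rose 2.79-fold, NDUFA11 rose 1.65-fold and COX8A, a cytochrome c oxidase subunit, rose 1.35-fold. The members that fell, named after their values were seen, were UQCRFS1, the iron-sulfur subunit of complex III, and the ATP synthase subunits ATP5F1 and ATP5J. Adjusted over the list alone, the counts were 4 up and 2 down for ribosomal proteins, 4 up and 0 down for translation factors, and 5 up and 4 down for oxidative phosphorylation.

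Camera called the ribosomal protein list as higher (adjusted p = 0.0156), but not with the correlation estimated (adjusted p = 0.809 with an estimated correlation), with fry (adjusted p = 0.529), nor without batch A library 3 (adjusted p = 0.744) or batch B library 1 (adjusted p = 0.447). In settings chosen after the data were seen, its call was lost with an abundance trend removed (adjusted p = 0.451), and with counts mapped back through simulated merging of identifiers it was called as lower (adjusted p = 0.0339, and 0.897 with an estimated correlation; median log2 fold change -0.08). Translation factors had camera adjusted p = 0.676 and oxidative phosphorylation genes 0.259, and with merging mapped back the latter were called as lower (adjusted p = 0.00117, and 0.801 with an estimated correlation). For changes in either direction, fry called translation factors (adjusted p = 0.0392) and oxidative phosphorylation genes (0.0151) and did not call ribosomal proteins (0.162). EIF3B lost its call with DESeq2 (adjusted p = 0.134), without a filter (edgeR adjusted p = 0.137) and when thinned (0.432), and COX8A when thinned (0.0842). Calls were lost without either batch A library for RPS10 (edgeR adjusted p up to 0.201, also without batch B library 1), EEF2 (0.289, also without batch B library 2), EIF3B (0.431, also without batch B library 1 or 2) and COX8A (0.140), without batch A library 2 for RPL17 (0.120) and without batch A library 3 for EIF4A1 (0.0566).

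Metabolic and cell cycle lists held 1 to 4 called members each. PGAM1 fell from 221 ± 5.96 to 107 ± 20.1 CPM (SD, n = 2 and 3, edgeR adjusted p = 2.38e-09) and was the only called member of 18 tested glycolysis genes. HMGCS1, which makes a precursor of mevalonate, rose by 0.70, and INSIG1, a sterol-regulated retention protein, by 0.53, 2 of 23 tested cholesterol biosynthesis genes. Of 43 genes of G1/S and DNA replication, 3 rose and 1 fell, among them the helicase subunit MCM7 (0.45), the single-strand binding subunit RPA2 (0.46) and GINS2, a subunit of the replicative helicase complex (-0.58), and the remaining called member was MCM4, named after its values were seen. Of 54 G2/M genes, NUSAP1 rose (0.45) and UBE2C (-0.37) and CKS2 (-0.36) fell. HIST1H4C fell by 0.37 and was called among 4 tested replication-dependent histone genes. These counts were the same when adjusted over each list alone.

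None of these lists passed camera, with adjusted p = 0.722 for glycolysis, 0.289 for cholesterol biosynthesis, 0.645 for G1/S and 0.645 for G2/M, and the histone list had too few tested members for it. Fry called cholesterol biosynthesis for changes in either direction (adjusted p = 0.0392). Without batch A library 3, calls were lost for HMGCS1 (edgeR adjusted p 0.0874), GINS2 (0.0609), RPA2 (0.298) and MCM7 (0.385). INSIG1 lost its call without batch A library 2 or batch B library 3 (log2 fold changes of 0.33 and 0.35, edgeR adjusted p up to 0.519), CKS2 without batch A library 2 or batch B library 2 or 3 (0.427), UBE2C without any library except batch B library 3 (0.259), NUSAP1 without any except batch B library 1 (0.253), and HIST1H4C without either batch A library or batch B library 3 (0.225). DESeq2 did not call CKS2 (adjusted p = 0.0529), INSIG1 (0.190), NUSAP1 (0.190) or UBE2C (0.0723). NUSAP1 was also lost without a filter, with library totals, with limma-voom and when thinned (adjusted p 0.0556 to 0.161), INSIG1 without a filter (0.107), and CKS2, HIST1H4C and RPA2 when thinned (0.136, 0.123 and 0.113).

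The stress, immediate-early, hypoxia and proteasome lists held 2 called members each. DDIT4, an inhibitor of the mTORC1 pathway that belongs to the integrated stress and the hypoxia lists, rose 1.92-fold, from 84.6 ± 10.6 to 163 ± 14.7 CPM (SD, n = 2 and 3, edgeR adjusted p = 2.75e-06). PSAT1, an enzyme of serine synthesis, fell by 0.60 on the log2 scale, so that 1 gene rose and 1 fell of 23 tested in the integrated stress list. The small heat shock protein HSPB1 rose by 0.58 and the chaperone HSP90AA1 by 0.40, 2 of 19 cytosolic heat shock genes. EGR1 (2.83-fold, edgeR adjusted p = 4.87e-10) and the AP-1 subunit JUNB (2.82-fold, edgeR adjusted p = 0.0391) rose among 16 immediate-early genes. DDIT4 and PLOD2, a collagen-modifying lysyl hydroxylase (0.69), rose among 21 hypoxia genes. The proteasome subunits PSMA6 (-0.50) and PSMC1 (-0.61) fell among 29 proteasome genes.

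Camera called the immediate-early list (adjusted p = 0.0233), but not with the correlation estimated (adjusted p = 0.809 with an estimated correlation), with fry for one direction (adjusted p = 0.330), without batch A library 2 (adjusted p = 0.678), without batch B library 1 (adjusted p = 0.328) or with the GC trend removed (adjusted p = 0.0763). Camera adjusted p was 0.83 for the integrated stress list, 0.645 for heat shock, 0.239 for hypoxia and 0.654 for the proteasome. For changes in either direction, which compares a list with no other genes, fry called hypoxia (adjusted p = 0.000144), immediate-early genes (0.00298), heat shock (0.0151) and the proteasome (0.0392), and not the integrated stress list (0.0694). Adjusted over the list alone, 2 rose and 1 fell in the integrated stress list, 3 rose and 1 fell in heat shock, 2 rose in each of the immediate-early and hypoxia lists, and 3 fell in the proteasome list. JUNB and PLOD2 lost their calls without either batch A library or batch B library 3 (edgeR adjusted p up to 0.406 and 0.153), HSP90AA1 without any library except batch B library 3 (0.316), and PSMC1 without batch A library 3 or batch B library 2 (0.407). DESeq2 did not call PLOD2 (adjusted p = 0.121) or PSMC1 (0.125). PLOD2 was also lost without a filter (edgeR adjusted p = 0.0600), PSMC1 when thinned (0.174), and JUNB without a filter (0.0612) and with limma-voom (0.0762).

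Nuclear long non-coding RNAs and the cytoskeleton were further groups with called members. MALAT1 rose by 0.79, from 92.8 ± 57.1 to 165 ± 21.6 CPM, and NEAT1, the scaffold of paraspeckles, by 0.41 (SD, n = 2 and 3), 2 of 7 tested nuclear long non-coding RNAs and 2 when adjusted over the list alone. DESeq2 called neither gene (adjusted p = 0.392 and 0.546), and NEAT1 was not called without a filter on low counts (edgeR adjusted p = 0.0556). Camera did not call the list (adjusted p = 0.0705, and 0.809 with an estimated correlation). It did without batch A library 3 (adjusted p = 0.0150, and 0.978 with an estimated correlation), without batch B library 2 (0.0461, and 0.918) and with the GC trend removed (0.0221, and 0.768). The NEAT1 libraries of the batches overlapped, and without batch A library 2 the log2 fold change was 0.34 for MALAT1 (edgeR adjusted p = 0.470) and 0.13 for NEAT1 (0.818), which also lost its call without batch B library 1 (0.25, 0.272). Without batch A library 3 they were 1.64 and 0.83, both called. Of 35 actin and tubulin cytoskeleton genes, the actin crosslinker FLNA rose by 0.67, and tropomyosin TPM3 (-0.51) and the myosin light chain MYL12B (-0.44) fell, against 3 up and 3 down adjusted over the list alone (camera adjusted p = 0.83, and 0.0458 with fry for changes in either direction). FLNA and TPM3 lost their calls without batch A library 2 (edgeR adjusted p = 0.161 for each), and MYL12B without any library except batch B library 1 (up to 0.246). MYL12B was also lost with DESeq2 (adjusted p = 0.160), without a filter (edgeR adjusted p = 0.0668) and when thinned (0.192), and FLNA when thinned (0.0778).

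Of the 28 gene lists, 12 had no called member. Among them, CANX and SEC61B of the 23 endoplasmic reticulum chaperone and unfolded protein response genes had log2 fold changes of -0.09 and -0.15 (camera adjusted p = 0.66). CCT7 and CCT4 of the 8 genes of the CCT chaperonin, which folds actin and tubulin, had 0.09 and 0.07 (0.645). For the 17 p53 targets, CCNG1 and MDM2 had 0.10 and -0.24 (0.645). For the 8 interferon response genes, IFITM2 and IFITM1 had 0.00 and -0.13 (0.807). SNRPD2 and SNRPE of 45 splicing genes had 0.03 and -0.07 (0.645). NPM1 and FBL of 31 nucleolar genes had 0.02 and 0.32 (0.807). GNB2L1 and SNHG8 of 15 host genes of small nucleolar RNAs had 0.13 and -0.24 (0.645), and SOX4 and UCHL1 of 9 neuronal lineage genes, some of which HEK293 cells express, had 0.24 and 0.13 (0.654). Of these lists with no called member, fry called the neuronal one for changes in either direction (adjusted p = 0.0171). FBL, with an edgeR adjusted p = 0.0832, was called without batch B library 3 (0.0363), with library totals in place of TMM (0.0414), at a mean count of at least 20 (0.0354), with limma-voom (0.0355), with the abundance trend removed (0.000487) and with merging mapped back (0.0220). SNHG8 was called with merging mapped back (0.0230) and SOX4 with the abundance trend removed (0.0291). NPM1, with an edgeR adjusted p = 0.967, turned to -0.28 with merging mapped back and was called as lower (0.0114).

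Markers of other cell types were low in both batches. Summed over each list, fibroblast and mesenchymal markers stood at 181 ± 1.02 CPM in batch A and 212 ± 32.8 CPM in batch B, epithelial and keratin markers at 117 ± 17.4 and 115 ± 20.6, leukocyte markers at 189 ± 5.72 and 208 ± 24.8, and erythroid and endothelial markers at 33.5 ± 12.4 and 45.6 ± 7.62 (SD, n = 2 and 3). Exact two-sided permutation p was 0.4, 0.9, 0.5 and 0.3. The leukocyte sum came mostly from CST3, a widely expressed protease inhibitor, at 166 ± 18.7 and 183 ± 25.5 CPM. SPARC and COL6A1 led the fibroblast list with log2 fold changes of -0.01 and 0.73, KRT18 and KRT8 the epithelial list with -0.01 and 0.04, and EGFL7 the endothelial list with 0.44. None of these genes was called, and adjusted over the list alone 1 fibroblast marker, COL6A1, was called, as it was over all genes without batch B library 3.

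The batches also differed in level by the GC content of transcripts. Genes in the highest quintile of GC content had a median log2 fold change of 0.18, with 80 called higher and 10 called lower, and genes in the lowest quintile had -0.07, with 16 higher and 42 lower. The median deviation of genes from their own mean over the 5 libraries was also compared between these quintiles. The highest quintile minus the lowest gave -0.12 and -0.14 in the batch A libraries. In the batch B libraries it gave 0.10, 0.09 and 0.09 on the log2 scale (exact two-sided permutation p = 0.1, the smallest possible). Deviations are centered over the libraries, so their signs show only how the batches differ from each other. After a GC trend was removed from each library, a setting chosen after the data were seen, 311 genes were called, 140 higher and 171 lower. The log2 fold changes of JUNB (1.26, edgeR adjusted p = 0.125), EIF3B (0.34, 0.0906), CKS2 (-0.30, 0.101), HIST1H4C (-0.33, 0.0631) and MYL12B (-0.38, 0.0906) were then nearer to 0 and no longer called. RP11-538P18.2 and AC006509.7 have no GC value and stayed at 2.32 and 2.15, and their adjusted p crossed the threshold, from 0.0470 to 0.0549 and from 0.0479 to 0.0560. With GC and length trends removed together, the log2 fold change of MT-TH went from 2.31 to 1.5 (edgeR adjusted p = 0.175) and that of FLNA from 0.67 to 0.39 (0.169), and both lost their calls. Calls were also lost, with adjusted p just past the threshold, for COX8A (0.44 to 0.33, edgeR adjusted p = 0.0568), MCM7 (0.45 to 0.34, 0.0558), RPS21P4 (2.35 to 2.08, 0.0590) and UBE2C (-0.37 to -0.33, 0.0523). With the abundance trend removed, calls were lost for RP11-538P18.2 (2.19, edgeR adjusted p = 0.0872), AC006509.7 (2.04, 0.0813) and MYL12B (-0.40, 0.0535).

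**Figure D5:**
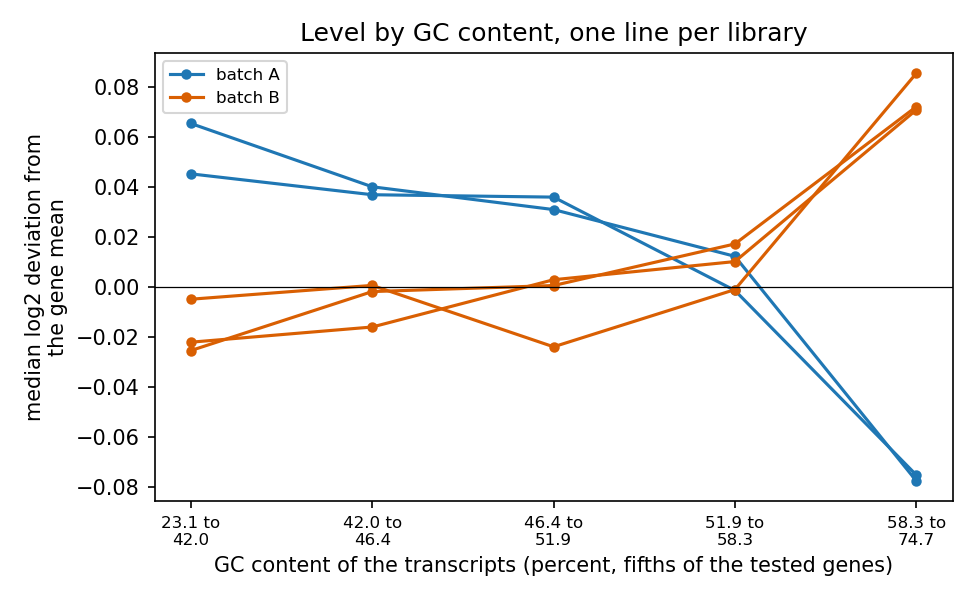
Median log2 deviation of genes from their own mean over the 5 libraries (vertical axis) in quintiles of transcript GC content (horizontal axis, percent), one line per library colored by batch. In the highest quintile both batch A libraries lie near -0.08 and the 3 batch B libraries between 0.07 and 0.09.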

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

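Removal of GC, length or abundance trends and the inversion of identifier merging were chosen after the data were seen. The count of 387 called genes ranged from 138 to 333 when each library was left out (79 to 170 higher, 58 to 163 lower), and every named gene called at the start kept its direction in each of those fits that tested it. Those fits reuse the libraries by which these genes were chosen, so the kept direction is largely fixed by the choice and is no separate evidence. The count of called genes was 178 after thinning (96 higher, 82 lower), where fewer counts remain, and 111 with DESeq2 (64 higher, 47 lower). Without a filter 121 were higher and 138 lower, and with GC and length trends removed 120 were higher and 180 lower. The count was 407 at a mean count of at least 20 (220 higher, 187 lower) and 410 with library totals (178 and 232). It was 453 with the abundance trend removed (256 and 197) and 502 with merging inverted (223 and 279). The cause of these shifts was not tested. Of the 387 genes, 375 were called with DESeq2 size factors, 356 with library totals, 337 with limma-voom, 382 after the collision correction, 265 with the GC trend removed, 349 with the length trend removed, 357 with the abundance trend removed and 377 with merging inverted. No paired analysis was possible because the deposited columns carry no replicate number of the labels, so a replicate block for the gene test and the list tests was not run. Scaling to the 33 spike-in counts of batch B moved the median log2 fold change of all genes to 9.03, with 9214 called higher (100%) and 0 lower, a shift that follows from the near absence of spike-ins. On that scale values turned positive for RP11-384C4.3 (6.47), RPL23AP3 (5.82), DBNDD2 (6.79), RPL4P4 (6.10), NDUFAF4 (7.43), RPL21P28 (7.44), CTD-2319I12.1 (7.22), AC004057.1 (7.73), AL354822.1 (7.16), RP11-106A1.2 (7.24), AC020983.5 (7.32), RPL17 (8.71), PGAM1 (8.09), GINS2 (8.65), UBE2C (8.72), CKS2 (8.78), HIST1H4C (8.87), PSAT1 (8.47), CANX (9.02), SEC61B (8.88), PSMA6 (8.62), PSMC1 (8.42), MDM2 (9.15), IFITM2 (8.88), IFITM1 (8.89), SNRPE (9.07), SNHG8 (8.93), TPM3 (8.69), MYL12B (8.53), SPARC (8.88) and KRT18 (9.24). Called lists numbered 0 with an estimated correlation, 0 with fry and 1 to 4 when libraries were left out. With merging inverted, the ribosomal protein list was called as lower (adjusted p = 0.0339, and 0.897 with an estimated correlation, over a range of 2.21e-05 to 0.809 in its other alternatives), its share differed by -1.48 percentage points, the shares of mitochondrial mRNAs and of the 10 most abundant genes by 3.28 and 3.77 points, and NPM1 turned to -0.28 and was called (edgeR adjusted p = 0.0114, over a range of 0.532 to 0.985 in its other alternatives except spike-in scaling). Without the 10 most abundant genes, nearly all of them such mRNAs, the mitochondrial share differed by 0.151 points. Calls were lost for 18 of 47 named genes with DESeq2, 12 of 59 after thinning, 10 of 67 with limma-voom, 9 of 67 without a filter, 12 of 67 with GC and length trends removed, and 33 of 65, 28 of 65, 16 of 66, 13 of 65 and 9 of 63 without batch A library 3 or 2 or batch B library 2, 1 or 3. The difference in genes detected was -734 without thinning, which follows depth, and -58.2 to 227 when libraries were left out. The spike-in ratio was 83.7 to 178 in those fits, all above 1, and 175 relative to mitochondrial mRNA counts. At pair sums of at least 100 the chi-square ratio was 1.69 within and 3.68 between batches, and at a pseudocount of 10 CPM Pearson's r was 0.978 and 0.975, because low counts then weigh less. At the depth, spread and number of these libraries the simulation found 32.8% of 1.5-fold changes. That share covers only genes with an expected mean count of at least 20. What each of depth, spread and number limits was not separated.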

Other observations

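The tests in this part were chosen after the results they bear on were seen. This includes removal of the GC trend and of the length trend. Only the bounds on the share of calls kept after each removal, for GC content and for length, were set before those counts were obtained. The bound for GC content as the whole cause was set afterwards. Rows annotated as pseudogenes were called more often than other rows, 24 of 153 (15.7%, 12 higher and 12 lower) against 363 of 9062 (4.01%), an odds ratio of 4.46 (95% interval 2.72 to 7.03, Fisher's exact test p = 1.98e-08), and genes are not independent.

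The 387 called genes differed in GC content by direction, with a median of 56.7% in the 181 higher and 46.6% in the 176 lower genes that have a GC value. Across 8982 tested genes log2 fold change followed GC content with a Spearman rho of 0.225. For the GC content of the 200 bases at the 5' end of transcripts, rho was 0.0866. With the GC trend removed 265 of the 387 were still called, among them 26 of the 30 without a GC value, which the correction cannot move. Of the 357 with one, 239 were still called, 114 higher and 125 lower, which argues against GC content as the whole cause. The shares of 68.5% of all and 66.9% of these 357 lie between the bounds set for most of the calls and for few of them, so a part played by GC content stays open. Transcript length is argued against as the main cause over the 387 genes, since 349 were still called with the length trend removed, 319 of them among the 357 genes with a length (89.4%), but the short MT-TS2, MT-TT and SNORD13 went from 2.49, 2.51 and 2.57 to 1.62, 1.68 and 1.94, and MT-TH lost its call (2.31 to 1.51, edgeR adjusted p = 0.141). The batch is the only grouping the labels give, so culture, lysis and library preparation cannot be told apart and no biological explanation was tested.

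Of the mitochondrially encoded transcripts, 11 of 13 mRNAs and 10 of 13 tRNA rows were called higher in batch B, although the mRNA list was not called with an estimated correlation (adjusted p = 0.809), and a ceiling on counts may raise abundant genes in the shallower libraries. Other genes of like mean count had a median log2 fold change of 0.25 beside the 12 mRNAs that have such genes. The mRNAs exceeded them by a median of 0.35 (SD 0.16, 11 of 12 above). Several mRNAs shared the same comparison genes, so these differences are not independent. For mRNAs with counts near those genes, this argues against the ceiling as the whole cause. The most abundant mRNAs had only genes of lower count for comparison and MT-CO2 none, so the ceiling stays open for them. In batch A library 2 and batch B library 3, of nearly equal depth, the median log2 ratio was 0.16, with all 13 mRNAs higher in batch B. A ceiling would also make this ratio smaller. With counts mapped back through simulated merging of identifiers, the share of these mRNAs in that pair was 7.23% and 9.85%, against 2.80% and 3.16% as deposited. Their median log2 fold change between the batches was then 0.59. These values rest on the simulation and do not settle the question for the most abundant mRNAs. The 13 tRNA rows, with counts of at most 220, exceeded genes of like count by a median of 1.59 (SD 0.86, 13 of 13 above). GC content and length are argued against as the whole cause for the mRNAs, whose median log2 fold change of 0.54 was 0.59 with the GC trend removed and 0.52 (SD 0.19) with the length trend removed. For the tRNA rows a length effect cannot be told apart from a rise of their own, since their median went from 1.73 to 0.92 (SD 0.83) with the length trend removed but 13 of the 16 tested genes that short are these rows, and differences in the cells or in the recovery of mitochondrial RNA stay open and were not tested.

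Counts of abundant genes rose less with depth than other counts, by a mean of 0.20 on the log2 scale over the 4 within-batch pairs, for 89 genes with a mean count over 800 against 5418 genes with 20 to 200. A candidate explanation is that identifiers 1 mismatch apart were merged, since a simulation of merging among the 20736 possible identifiers levels off near 2909 and the highest count was 2293. Mapping counts back through that simulation brought the mean absolute deficit to 0.0677 (SD 0.0478), although the pair of batch B libraries 1 and 2 went from -0.17 to 0.12. Collisions of identical identifiers used evenly are argued against, because their correction left 0.191 (SD 0.0813). Uneven use of identifiers and other properties of abundant genes stay open.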
